A study of Mus musculus with 18 samples.

How the data were processed

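PolyA-selected RNA of mouse heart ventricles at E14.5 was sequenced in 18 libraries of 5 genotypes. Per the labels' protocols, ventricles were frozen, RNA was purified with a column kit and accepted at an RNA integrity number above 8.5, and libraries were made with a directional kit. The groups and replicate numbers came from the sample titles: 3 wild-type (WT) libraries, 3 labelled Irx3KO, 3 labelled Irx4KO, 3 labelled heterozygous for both genes (double heterozygotes) and 6 labelled knockout for both genes (DKO). The labels do not say whether each library came from a separate embryo, so p-values measure the spread between these libraries, which may be technical.

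The authors deposited for each library a table of estimated counts per transcript. Per the file headers, these are kallisto tables with transcript length, effective length, estimated counts and TPM. The submitters' processing notes name kallisto 0.42.2 and the mm9 mouse genome. The transcript release and the strand setting are not given in the sources used here. TPM is a transcript's share of the library after scaling for length. Per the file headers, the TPM values are already scaled for transcript length and library total, and they were used only to rebuild counts in an alternative.

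The tables listed 88943 transcripts. Of these, 78030 (87.73%) were tied to a gene by their identifier in GENCODE M21 (GRCm38), which is not the genome build of the submitters, so no coordinates are given. The other 10913 transcripts held between 6.43% and 6.77% of the counts of a library and entered no gene-level test except in an alternative. Estimated counts were summed over the transcripts of each of 28563 genes and rounded to whole numbers. Library totals ran from 26721576 to 45946741 estimated counts. No 2 libraries of a group agreed within sampling noise (the smallest chi-square per gene was 6.37), which gives no sign of a repeated library and does not show that libraries came from separate embryos.

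Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (robust), with TMM normalization, filterByExpr, all 18 libraries in 1 fit with genotype as the only term, and Benjamini-Hochberg adjustment at a threshold of 0.05. This left 16607 genes and a common dispersion of 0.0276. All gene-level adjusted p-values below come from this test unless another tool is named. The standard error of a log2 fold change is its size divided by the square root of F. Levels are CPM, counts scaled to a common library total, with TMM factors, as mean ± SD. Fitted fold changes use a prior count of 0.125. The contrasts were DKO against each other genotype, each other genotype against WT, and the Irx3 by Irx4 interaction, which is the DKO minus Irx3KO difference less the Irx4KO minus WT difference.

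A total of 26 gene lists with 358 entries was tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists. Of these names, 5 had no match (Ahsp, Aldoa, Hbb-b1, Hbb-b2 and Xist). The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. That rule names Irx3 and Irx4 in every comparison. In DKO against WT it adds the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM in a compared group and no overlap between the groups. In the other comparisons it adds 5 of each, and from each list up to 4 members with the smallest p. Gene models without a descriptive symbol and Y-linked genes were passed over, and a few genes that the rule names are not reported here. The non-overlap condition has no meaning for the interaction and was not applied there.

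The libraries fell into 2 sets that the labels do not name, so a second fit, chosen after the data were seen, held the set as a term. In this fit, called within sets, DKO is compared with WT over the libraries of set 1, and with the other genotypes over those of set 2, and the dispersion (0.0207) is shared by all libraries. Each single knockout and the double heterozygote can be set against WT in it only by way of the DKO libraries of both sets. The same naming rule was applied to it, the chromosome and transcript tests were added, and 3 comparisons inside set 2 (Irx3KO with Irx4KO, and each with the double heterozygotes) were made, all chosen after the data were seen.

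The alternatives tried were RLE size factors, DESeq2 1.42.0, limma-voom with quality weights, no filter on low counts, a filter of 1 CPM in 3 libraries, counts rebuilt from TPM, a fit of only the compared groups, a covariate for embryo sex, the replicate number as a block, every choice of 3 of the 6 DKO libraries (20 choices) and leaving out each library in turn. The sex covariate had been planned as Y-linked genes less Xist and holds 4 Y-linked genes only, because Xist was not matched. Added after the data were seen were the set term, libraries of 1 set only, the trends of each library on transcript length and GC removed by offsets, and unmatched transcripts kept as features.

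The tests were also run on simulated data, after the real libraries had been fitted. Means and library sizes came from the real libraries and dispersions from the fit within sets. In these data 200 genes were changed by 1.5, 2 or 4-fold in DKO. With no difference between the sets, the planned fit of DKO against WT recovered 89.6% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold, and called 5 of 16190 unchanged genes. With the set difference of the real data simulated, it recovered 71.6%, 89.6% and 98.5% and called 27 of 16191 unchanged genes. That difference was taken between the mean levels of all libraries of each set, so it also holds differences between their genotypes. With that difference the planned fit also called 804 unchanged genes in Irx3KO against WT, 865 in Irx4KO against WT, 747 in the double heterozygotes against WT and 2084 in the interaction. The fit within sets called 11 unchanged genes in DKO against WT and recovered 74.6%, 91.0% and 100%. It recovered 6.0% of genes changed 1.5-fold, 49.3% of those changed 2-fold and 90.9% of those changed 4-fold in the interaction. A planted list of 12 atrial markers was found by camera in every simulated case, beside 5 other lists in the planned fit with the set difference. Every gene was simulated with 1 dispersion for all libraries, while the real groups differed in spread. The chi-square per gene was 6.37 between Irx3KO 1 and 2 and 64.22 between DKO 5 and 7. The simulated shares therefore do not show how well a dispersion shared by all groups serves DKO against WT. Each gene was simulated independently of the others. The simulation therefore does not show how often camera calls an unchanged list whose genes vary together.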

Results

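RNA of mouse heart ventricles at E14.5 was measured by polyA RNA-seq in 18 libraries, to compare the loss of Irx3, of Irx4 and of both genes, which encode Iroquois homeobox transcription factors, in the wall of the ventricle. There were 3 WT libraries, 3 labelled Irx3KO, 3 labelled Irx4KO, 3 double heterozygotes and 6 DKO libraries. Estimated counts per library ran from 26721576 (double heterozygote 4) to 45946741 (DKO 10). Y-linked genes summed to 0.88 CPM in WT 3, 1.10 CPM in DKO 4 and 1.42 CPM in double heterozygote 2, and to between 96.72 and 300.63 CPM in the other 15 libraries.

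The libraries fell into 2 sets that the labels do not name. Set 1 held WT 1, 2 and 3 with DKO 5, 7 and 10, and set 2 held the other 12 libraries, so that only DKO was in both. Spearman's rho between a library's deviation from the mean and transcript length, over 11252 genes, was between -0.579 and -0.353 in set 1 and between 0.059 and 0.573 in set 2. Ward and complete-linkage clustering of the libraries gave the same sets for 18 of 18 libraries. Within the DKO genotype, 3119 of 16607 genes differed between the sets, 1501 higher in set 1 and 1618 higher in set 2, with median longest transcripts of 1847 and 5800.5 nt. Comparisons of WT with Irx3KO, Irx4KO or double heterozygotes therefore coincide with the set, and the count of genes in each comparison is given from the planned fit and from the fit within sets.

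**Figure D1:**
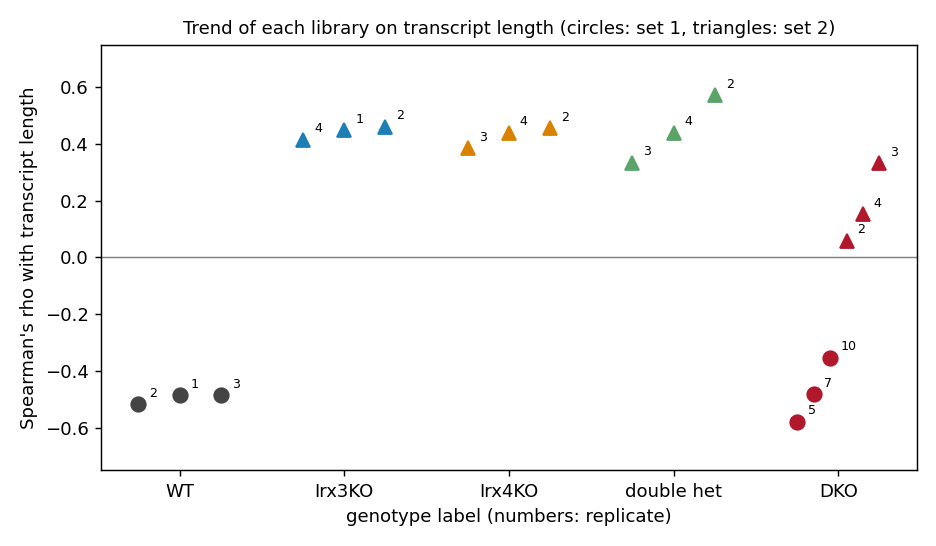
Spearman's rho of each library's deviation with transcript length (y axis) by genotype label (x axis, replicate numbers beside the points), with circles for set 1 and triangles for set 2. The 6 libraries of set 1 lie between -0.579 and -0.353 and the 12 of set 2 between 0.059 and 0.573.

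Irx3 was low in every library labelled with a homozygous Irx3 mutation, while Irx4 counts were higher, not lower, in libraries labelled Irx4KO or DKO. Irx3 was at 24.9 ± 3.28 CPM in WT (SD, n = 3), 24.9 ± 2.39 in Irx4KO (n = 3), 13.1 ± 0.257 in double heterozygotes (n = 3), 2.83 ± 0.269 in Irx3KO (n = 3) and 3.71 ± 0.413 in DKO (n = 6). Irx4 was at 95.6 ± 26 CPM in WT, 145 ± 11.6 in Irx3KO, 185 ± 8.05 in double heterozygotes, 225 ± 12.6 in libraries labelled Irx4KO and 241 ± 24.9 in libraries labelled DKO. The 9 libraries labelled with a homozygous Irx4 mutation were all above all 3 WT libraries. Within sets Irx4 was higher in libraries labelled DKO than in WT by 1.40 ± 0.14 (log2 fold change ± SE, 3 against 3 libraries, adjusted p = 1.0e-04), and the adjusted p was 0.064 in a fit of the set 1 libraries alone. Transcript Irx4-202 held 80.95% of the Irx4 counts in WT (76.94% to 86.6%) and 91.25% in DKO of set 1 (89.95% to 92.33%). The labels do not say which part of Irx4 was removed, so its count checks neither the Irx4 labels nor a direction, and Irx4KO and DKO stand below for libraries so labelled.

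**Figure D2:**
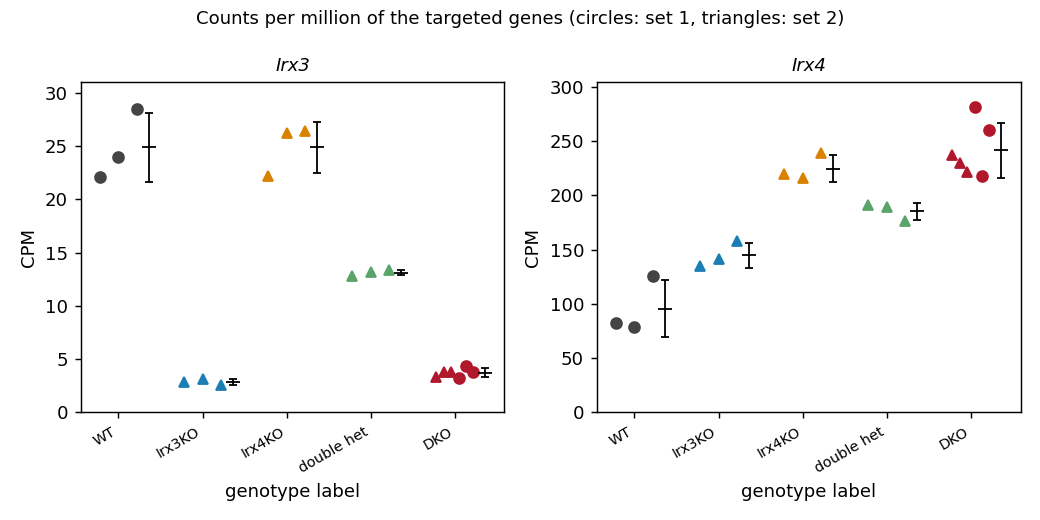
CPM of Irx3 and Irx4 (y axes) in each library by genotype label (x axis), with circles for set 1, triangles for set 2 and bars for the mean and SD. Irx3 lies at 24.9 CPM in WT and 3.71 CPM in DKO, and Irx4 at 95.6 CPM in WT and 241 CPM in libraries labelled DKO.

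DKO ventricles were compared with WT to ask what changes when both genes are lost. Gja1, which encodes the gap junction protein connexin 43, fell from 550 ± 64.9 CPM in WT to 347 ± 34.8 in DKO (SD, n = 3 and 6; log2 fold change -0.66 ± 0.083 SE, adjusted p = 0.00094), and within sets by 0.57 ± 0.086 (adjusted p = 0.0029). Pln, the inhibitor of the sarcoplasmic calcium pump, fell from 1870 ± 171 to 1380 ± 31 CPM (-0.43 ± 0.062, adjusted p = 0.0024, within sets -0.43 ± 0.07, adjusted p = 0.0049). Tbx2, a repressor of chamber genes in the atrioventricular canal, rose from 23.2 ± 2.83 to 39.9 ± 8.09 CPM (0.78 ± 0.15, adjusted p = 0.019, within sets 0.96 ± 0.14, adjusted p = 0.0023). Kcnh7, a voltage-gated potassium channel, rose from 8.88 ± 0.924 to 19.5 ± 4.13 CPM (1.13 ± 0.15, adjusted p = 0.0018, within sets 0.92 ± 0.14, adjusted p = 0.0037). The lysozyme Lyz1 fell from 5.63 ± 1.54 to 1.09 ± 0.266 CPM (-2.37 ± 0.21, adjusted p = 1.4e-05, within sets -2.51 ± 0.26, adjusted p = 1.0e-04), though its near-identical copy Lyz2 makes its count uncertain. With only WT and DKO in the fit the adjusted p of Gja1 was 0.065, of Kcnh7 0.065, of Pln 0.087 and of Tbx2 0.18, and over the libraries of set 1 alone it was 0.14, 0.089, 0.17 and 0.051. Tbx2 lost the call of the planned fit without WT 1 (0.15) or WT 2 (0.12).

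In the planned fit 105 genes passed in DKO against WT, 61 higher and 44 lower, and the fit within sets called 239, 107 higher and 132 lower, with 84 in both. The balance within sets was not stable. It was 284 higher and 162 lower with length and GC trends removed, 408 and 178 without DKO 5, and 244 and 308 without DKO 10. Rises also prevailed by DESeq2 and limma-voom, and falls with RLE size factors, the sex covariate and counts rebuilt from TPM. In set 1 only WT 3 had few Y-linked counts, so by this measure embryo sex was not balanced between WT and DKO. With the sex covariate the 239 genes became 183, 82 higher and 101 lower. By the naming rule, the rises in the planned fit were Mt3 2.48, Tnni2 1.86, Pcdhac2 1.71, Irx4 1.34, Hmcn2 1.24, Kcnh7 1.13, Ntsr1 1.12, Nefl 1.01, Bbs2 0.95 and Rgs6 0.94 (log2 fold changes, adjusted p from 2.6e-05 to 0.028). They include the metal-binding protein Mt3, the fast-muscle troponin Tnni2, the protocadherin Pcdhac2, the neurotensin receptor Ntsr1, the neurofilament Nefl and the ciliary BBSome member Bbs2. The falls were Irx3 -2.74, Lyz1 -2.37, Lyz2 -1.80, Asb11 -1.51, Wif1 -1.46, Ddc -1.41, Gtsf1 -1.37, Pde1c -1.16, Lgi3 -1.01 and Plppr1 -0.82 (adjusted p from 1.6e-11 to 0.028). Among these, Ddc is the decarboxylase that makes dopamine and serotonin, Wif1 a secreted Wnt inhibitor and Pde1c a cyclic-nucleotide phosphodiesterase. All 20 were also past the threshold within sets, at adjusted p from 2.0e-09 to 0.04. The naming rule applied within sets added Nefm 2.30, Mybphl 1.32, Klf14 1.25, Dusp26 1.24, Lyve1 1.21, Slc15a2 -3.40, Gbp4 -1.98, Angpt2 -1.83, Grik3 -1.31 and Ntrk2 -1.31. Of 43 named genes called within sets, list members included, 16 passed without each library in turn: Irx3, Irx4, Mt3, Pcdhac2, Kcnh7, Ntsr1, Nefl, Bbs2, Lyz1, Plppr1, Gja1, Pln, Tbx2, Stard10, Lyve1 and Angpt2. Of the other 27, 26 lost the call without WT 1, 15 without WT 3, 10 without WT 2, 10 without DKO 7, 8 without DKO 10, 5 without DKO 5, 3 without DKO 2, and 2 each without DKO 3 or DKO 4. Without WT 1 the adjusted p was 0.056 for Tnni2, 0.055 for Asb11, 0.066 for Wif1, 0.12 for Ddc, 0.14 for Gtsf1, 0.17 for Pde1c and 0.18 for Lgi3. The count of 105 became 26 without WT 1, 62 without WT 2, 63 without WT 3 and 607 without DKO 5, and that of 239 within sets became 67 without WT 1, 124 without WT 3, 552 without DKO 10 and 586 without DKO 5. The calls rest on the spread pooled over all groups, since a fit of WT and DKO alone called 6 genes and a fit of the set 1 libraries alone called 16.

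**Figure D3:**
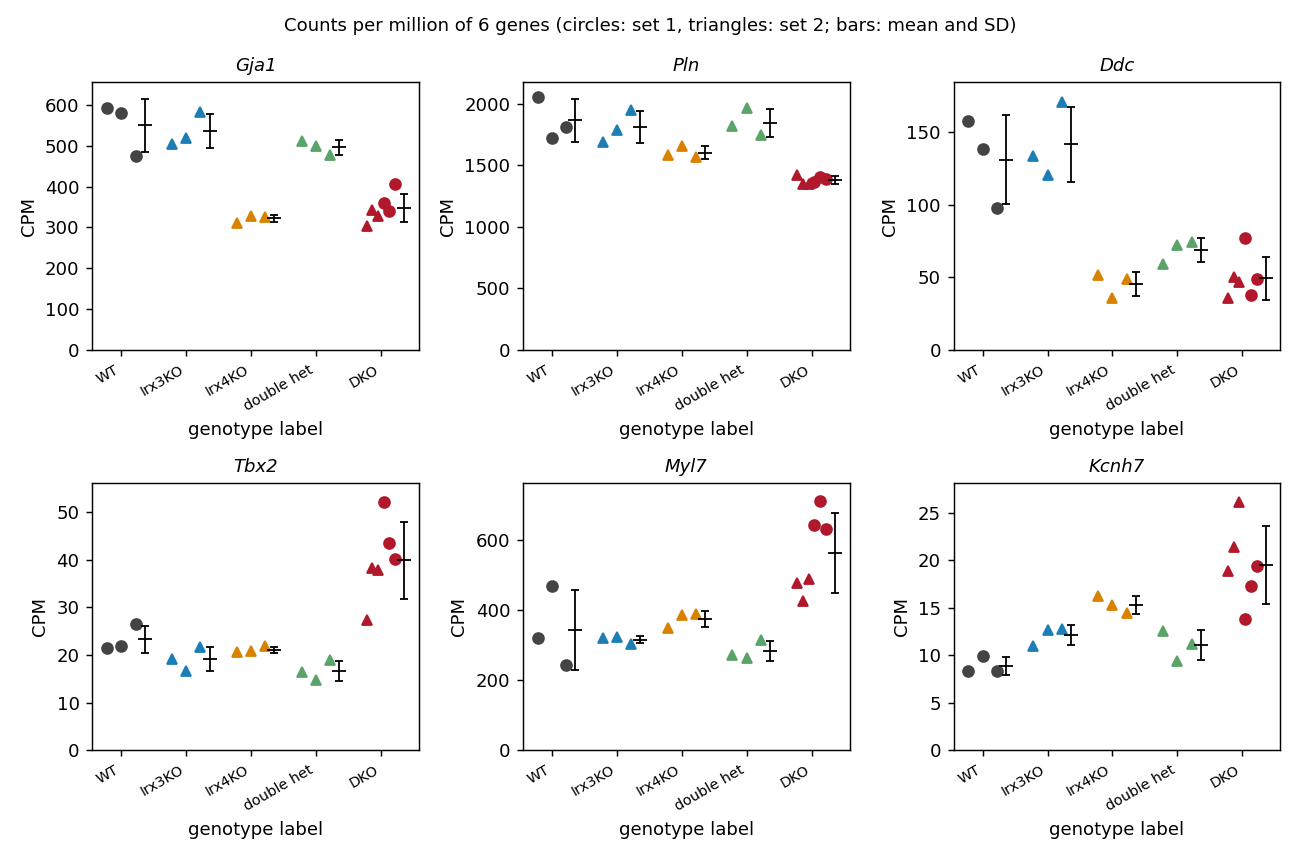
CPM (y axes) of Gja1, Pln, Ddc, Tbx2, Myl7 and Kcnh7 in each library by genotype label (x axis), with circles for set 1, triangles for set 2 and bars for the mean and SD. Gja1 lies at 550 CPM in WT, 536 in Irx3KO, 322 in libraries labelled Irx4KO and 347 in DKO.

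Contractile genes and atrial markers ranked higher as groups in DKO than in WT by camera at its preset correlation, while most of their members did not pass singly. Other divisions of the same WT and DKO libraries passed up to 11 lists in the planned fit with 0 genes called. The number of lists that passed therefore does not exclude chance. With an estimated correlation the call held in the planned fit for atrial markers and cardiac transcription factors, and within sets for no list. Of 30 sarcomere genes 3 rose, none fell and 27 did not pass (7 rose when adjusted over the list alone). Myh6, the alpha-myosin heavy chain, was at 0.56 (adjusted p = 0.025), and the Z-disc protein Nebl at 0.51. The group was higher (camera adjusted p = 3.01e-07, adjusted p = 0.232 with an estimated correlation). None of 12 atrial markers passed over all genes, and 4 rose and 1 fell when adjusted over the list alone. The group was higher (camera adjusted p = 1.57e-04, adjusted p = 0.027 with an estimated correlation). Within sets 3 of them rose, among them the atrial light chain Myl7 (0.94 ± 0.16, adjusted p = 0.0091) and the lipid-transfer protein Stard10 (1.16 ± 0.18, adjusted p = 0.004). The atrial list was also planned as a check for atrial tissue in the dissection. Here and in the other DKO comparisons, such tissue cannot be told apart from a change within the ventricle. Of 17 cardiac transcription factors 2 rose (3 when adjusted over the list alone), Tbx5 by 0.39 (adjusted p = 0.013) and Gata6 by 0.28 (adjusted p = 0.021). The group was higher, with camera adjusted p = 1.57e-04 and adjusted p = 0.0142 with an estimated correlation. Of 28 conduction and ion channel genes 2 rose (Tbx5 and Tbx2) and Gja1 fell (5 and 4 when adjusted over the list alone). The group was higher, with camera adjusted p = 0.0215 and adjusted p = 0.338 with an estimated correlation. Of 22 growth factor signals of trabeculation Bmp5 and Bmp2 rose by 0.70 and 0.52 (3 when adjusted over the list alone), with camera adjusted p = 0.0127 and adjusted p = 0.338 with an estimated correlation. None of 7 compact myocardium markers passed, over all genes or when adjusted over the list alone, and the group was higher (camera adjusted p = 0.0306, adjusted p = 0.189 with an estimated correlation). Of 8 ventricular markers Pln fell, also when adjusted over the list alone, and the group was lower (camera adjusted p = 0.0306, adjusted p = 0.232 with an estimated correlation). None of 25 fatty acid oxidation and respiration genes passed in either way and the group was lower (median -0.063, camera adjusted p = 4.88e-04, adjusted p = 0.547 with an estimated correlation). Of the list members named, Myh6, Tbx5, Gata6, Bmp5, Bmp2 and Nebl lost the call of the planned fit without WT 1 (adjusted p from 0.11 to 0.21). They lost it without WT 2 as well (0.066 to 0.17), and Myh6, Nebl, Bmp5 and Bmp2 also without WT 3 (0.089 to 0.24). Bmp2 lost it without DKO 4 (0.068) or DKO 10 (0.072), and Nebl without DKO 2, DKO 3, DKO 4, DKO 7 or DKO 10 (0.054 to 0.093). Within sets Myl7 lost it without WT 1 (0.051). As groups, sarcomere genes, atrial markers and cardiac transcription factors passed without each library in the planned fit. Conduction genes lost the call without DKO 3 (0.119), DKO 10 (0.0864) or WT 2 (0.269), compact markers without DKO 3 (0.055), DKO 4 (0.058) or WT 2 (0.0564), and ventricular markers without DKO 3 (0.109), DKO 4 (0.058) or WT 1 (0.0814). Without WT 1 it was also lost by the growth factor signals (0.0817) and the fatty acid oxidation genes (0.0962).

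Markers of blood cells ranked lower in DKO beside these groups, by camera at its preset correlation only. Of 12 macrophage and leukocyte markers Lyz2 fell (5 fell when adjusted over the list alone), with a median of -0.475, camera adjusted p = 1.5e-07 and adjusted p = 0.232 with an estimated correlation. None of 11 erythroid markers passed in either way, and the group was lower, with a median of -0.395, camera adjusted p = 0.0127 and adjusted p = 0.441 with an estimated correlation. Within sets 6 lists passed, sarcomere genes (camera adjusted p = 1.13e-08), atrial markers (7.65e-04), cardiac transcription factors, erythroid markers and macrophage markers (each 0.0256) and neighbours of Irx4 (0.0307). None of them passed with an estimated correlation (adjusted p from 0.136 to 0.797). Of these, sarcomere genes and atrial markers passed without each library in turn, at most 1.8e-05 and 0.0247. The cardiac transcription factors lost the call without DKO 10 (0.254). The erythroid markers lost it without DKO 7 (0.198), DKO 10 (0.233) or WT 1 (0.0988), and the macrophage markers without DKO 7 (0.0983), DKO 10 (0.293) or WT 2 (0.943). The neighbours of Irx4 lost it without DKO 5 (0.104) or DKO 7 (0.0746). In the planned fit the macrophage markers passed without each library, and the erythroid markers did not without DKO 7 or WT 1 (each 0.0817). Cell cycle genes did not pass within sets with all libraries (0.595), yet passed as higher without DKO 5 (0.000293) and as lower without DKO 7 (0.00252), so no direction is given for them here. Other lists that passed within sets only when 1 library was left out were conduction genes (0.0403 without DKO 7), epicardial markers (0.0403 without DKO 7, 0.0329 without WT 2, 0.0452 without WT 3), extracellular matrix genes (0.0203 without DKO 10, 0.0116 without WT 2), fatty acid oxidation genes (0.0086 without DKO 7, 0.0324 without WT 2) and glycolysis genes (0.0445 without WT 2). In the planned fit 16 lists did not pass. Their camera adjusted p was 0.093 for cell cycle genes, 0.0932 for extracellular matrix genes, 0.0959 for neighbours of Irx4, 0.151 for calcium handling genes and for cushion and fibroblast markers, and 0.326 for epicardial markers. It was 0.35 for glycolysis and hypoxia genes, 0.378 for the Irx family and for endothelial and endocardial markers, 0.54 for Notch pathway genes, and 0.614 for smooth muscle and pericyte markers and for sex-linked genes. It was 0.619 for neighbours of Irx3, 0.709 for immediate early and heat shock genes, 0.742 for neural crest and neuron markers and 0.957 for trabecular myocardium markers. Of these, cell cycle genes passed without DKO 3 (0.0199), DKO 5 (0.000285), DKO 10 (0.0467) or WT 3 (0.0392), extracellular matrix genes without DKO 5 (0.0144), DKO 7 (0.0275) or WT 3 (0.0231), calcium handling genes without WT 1 (0.023), endothelial markers without WT 2 (0.0182), cushion markers and Notch pathway genes without WT 3 (0.035 and 0.0364), and neighbours of Irx4 without DKO 3 (0.0392). Over all genes Cacnb2 rose and Pln fell among calcium handling genes (4 rose and 2 fell when adjusted over the list alone) and the Notch ligand gene Jag2 rose (1 when adjusted over the list alone). Both rises were lost without WT 1 (Cacnb2 0.12, Jag2 0.088) or WT 2 (0.17 and 0.082), and that of Cacnb2 also without WT 3 (0.11) or DKO 4 (0.06). None of the members of the other 14 lists passed over all genes, where the Irx family list holds Irx1, Irx2, Irx5 and Irx6 and leaves out both targeted genes. When adjusted over the list alone 2 rose and 1 fell in the Irx family, 1 rose and 1 fell among trabecular markers, 1 rose each among epicardial and smooth muscle markers, 3 rose among neighbours of Irx4 and none passed in the remaining 9. Median, mean and test differed in sign for trabecular markers, Notch pathway genes, neural crest and neuron markers and sex-linked genes.

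DKO was compared with Irx3KO to ask what the second mutant gene adds to loss of Irx3. Gja1 was at 536 ± 41.5 CPM in Irx3KO and 325 ± 19.4 in DKO of set 2 (SD, n = 3 and 3) and fell by 0.72 ± 0.086 within sets (adjusted p = 0.0015; planned fit -0.63 ± 0.083, adjusted p = 0.0011). Pcdhac2 rose from 1.41 ± 0.297 to 5.19 ± 1.5 CPM (1.88 ± 0.24 within sets, adjusted p = 0.0024), and the neuronal receptor Gpr37 fell from 6.85 ± 0.376 to 2.07 ± 0.287 CPM (-1.72 ± 0.23, adjusted p = 0.003). Ddc fell from 142 ± 25.7 to 44.1 ± 7.66 CPM (-1.68 ± 0.26, adjusted p = 0.013), Tbx2 rose by 0.85 ± 0.14 (adjusted p = 0.011) and Pln fell by 0.40 ± 0.07 (adjusted p = 0.016), all within sets. Irx4 rose by 0.67 ± 0.14 (adjusted p = 0.045) and Irx3 was at 0.37 (adjusted p = 0.41). In the planned fit 284 genes passed, 145 higher and 139 lower, and the fit within sets called 63, 27 higher and 36 lower, of which 60 were in both. A fit of the set 2 libraries alone, which takes the spread from those libraries only, called 179. The naming rule also named Tnni2 at 2.26, Mab21l2 at 1.99, Mybphl at 1.21, Stard10 at 1.15, Wif1 at -1.77, Megf10 at -1.58 and Asb11 at -1.44 in the planned fit. Of these, Mab21l2, Mybphl, Stard10, Wif1 and Asb11 did not pass within sets (adjusted p from 0.052 to 0.2). Gja1, Pcdhac2, Gpr37 and Gtsf1 passed within sets without each library in turn. Ddc lost the call without DKO 2 (0.073), DKO 4 or Irx3KO 4 (each 0.071), and Tbx2 without DKO 3 (0.051), DKO 4 (0.071), Irx3KO 1 (0.074) or Irx3KO 2 (0.075). Pln lost it without DKO 3 or Irx3KO 2 (each 0.063), DKO 4 (0.099) or Irx3KO 4 (0.12). Megf10 lost it without DKO 4 or Irx3KO 4 (each 0.071). Irx4 and Tnni2 lost it without DKO 2, DKO 3 or DKO 4 or any Irx3KO library (0.053 to 0.24), and without DKO 10 (Irx4, 0.058) or DKO 7 (Tnni2, 0.056). Within sets, 7 lists passed camera. Cell cycle genes (camera adjusted p = 0.0121), atrial, cushion and fibroblast and epicardial markers were higher, and the Irx family, calcium handling genes and erythroid markers were lower. None passed with an estimated correlation (adjusted p from 0.368 to 0.689), and none of the 7 passed without each library. Cell cycle genes lost the call without DKO 2 (0.295), erythroid markers without DKO 2 (0.218) or Irx3KO 4 (0.0867), and the Irx family without DKO 3 (0.27) or Irx3KO 2 (0.166). Without DKO 4 or Irx3KO 4 it was lost by atrial markers (0.0686 and 0.148), epicardial markers (0.0907 and 0.218), cushion and fibroblast markers (0.0686 and 0.0867) and calcium handling genes (0.314 and 0.291), and without DKO 3 by atrial (0.066) and epicardial markers (0.159). Passing only with 1 library left out were, without DKO 2, conduction genes as higher (0.00532) and fatty acid oxidation genes (0.0227), neighbours of Irx4 (0.0345) and sex-linked genes (0.0375) as lower, without DKO 4 glycolysis genes as higher (0.00159), and sarcomere genes as higher without DKO 3 (0.0302), DKO 4 (0.0398) or Irx3KO 4 (0.0176). The planned count was between 52 (without Irx3KO 4) and 1413 (without DKO 3) with 1 library left out, 68 without Irx3KO 1, 69 without Irx3KO 2, 138 without DKO 10 and 472 without DKO 4. The count within sets was 15 without DKO 4, 19 without Irx3KO 4, 20 without Irx3KO 1, 24 without Irx3KO 2, 27 without DKO 2, 41 without DKO 3 and 142 without DKO 5.

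The comparisons of DKO with WT and of DKO with Irx3KO within sets compare no library in common, but both tests use each gene's spread over all libraries. A gene of low spread is more easily called in both, in the same or in opposite directions. The numbers given for independent lists are therefore no exact values for unrelated lists. Of the 239 genes called against WT, 210 had the same sign against Irx3KO, and 19 rose and 22 fell in both, where independent lists would share 0.17 and 0.29, with 0 in opposite directions. Shared falls included Gja1, Pln, Ddc, Lyz1, Gpr37, Trib2 and the potassium channel gene Kcnk3, and shared rises Tbx2, Kcnh7, Pcdhac2, Tnni2, Irx4 and the matrix gene Thbs4. Across all 16607 genes, which are not independent replicates, Pearson's r was 0.147 and Spearman's rho 0.269. Against Irx4KO, 171 of the 239 had the same sign, 2 rose and 1 fell in both, and r was 0.029. Against double heterozygotes, 200 had the same sign, 4 rose and 7 fell in both, and r was 0.102.

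**Figure D4:**
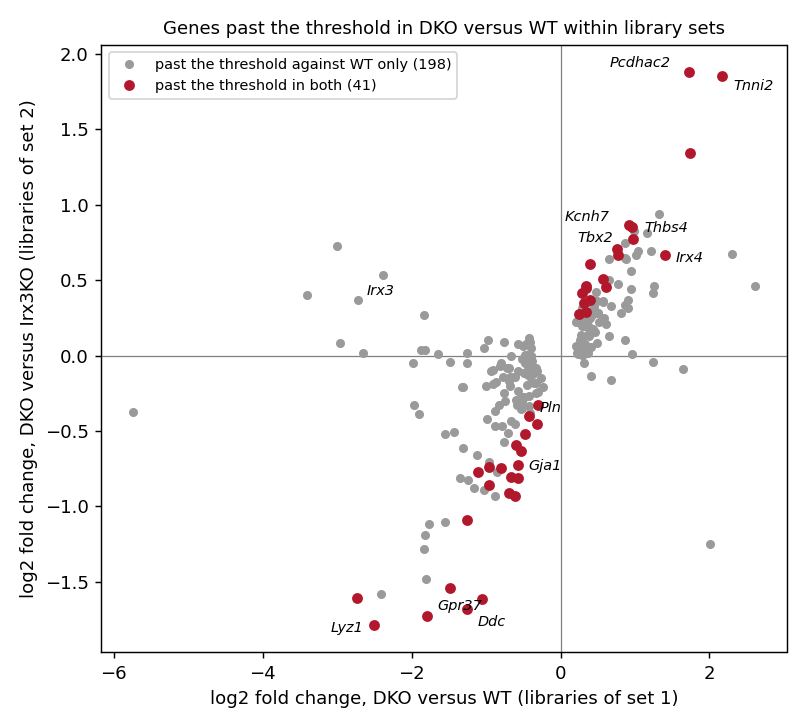
Log2 fold changes of the 239 genes past the threshold in DKO against WT within set 1 (x axis) against those of DKO against Irx3KO within set 2 (y axis), each point a gene. The 41 red genes pass in both, 19 upwards and 22 downwards, and 210 of the 239 have the same sign.

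DKO was compared with Irx4KO to ask what loss of Irx3 adds in libraries that both carry mutant Irx4. Irx3 fell from 24.9 ± 2.39 CPM in Irx4KO to 3.66 ± 0.29 in DKO of set 2 (-2.77 ± 0.13 within sets, adjusted p = 1.7e-09; planned fit -2.75, adjusted p = 1.6e-11). Mt3 rose from 1.14 ± 0.674 to 5.81 ± 0.61 CPM (2.35 ± 0.37 within sets, adjusted p = 0.037), Bbs2 from 8.29 ± 0.957 to 15.6 ± 1.26 CPM (0.91 ± 0.14, adjusted p = 0.037), and Adgre5, an adhesion receptor of leukocytes and other cells, fell from 74 ± 0.974 to 53.4 ± 2.51 CPM (-0.47 ± 0.075, adjusted p = 0.037). Irx4 did not differ past the threshold (0.03, adjusted p = 1.0). Gja1 was at 0.011 ± 0.086 (adjusted p = 0.996), Pln at -0.223 ± 0.07 (adjusted p = 0.724) and Kcnh7 at 0.532 (adjusted p = 0.645) within sets. A total of 12 genes passed in the planned fit, 4 higher and 8 lower, and the fit within sets called 4 of them, all named here, Irx3, Mt3, Bbs2 and Adgre5. Named in the planned fit alone were Tbx2 at 0.92, Jmjd7 at 0.72, Pdzrn3 at -0.81, Akr1b10 at -0.69 and Hif3a at -0.62, which did not pass within sets (adjusted p from 0.071 to 0.26). Ccl21a was also lower and is given without a fold, since it was near the floor in DKO and has near-identical copies. Irx3 passed within sets without each library. Mt3 lost the call without any compared library but Irx4KO 4 (0.057 without DKO 5 to 0.42 without Irx4KO 3), and Adgre5 without any but DKO 5 (0.061 without DKO 10 to 0.35 without Irx4KO 3). Bbs2 lost it without DKO 3 (0.15), DKO 4 (0.14), DKO 10 (0.061), Irx4KO 2 (0.17) or Irx4KO 3 (0.35). The planned count was 1 without Irx4KO 3, 4 without Irx4KO 2 or Irx4KO 4, 6 without DKO 10, 7 without DKO 7, 35 without DKO 2 and 1040 without DKO 3. Within sets 1 gene passed without DKO 3, DKO 4, DKO 10, Irx4KO 2 or Irx4KO 3, and 2 without DKO 7. Within sets, cell cycle genes (camera adjusted p = 1.7e-06) and glycolysis genes were higher and calcium handling and extracellular matrix genes lower as groups. None passed with an estimated correlation (adjusted p from 0.804 to 0.805), and glycolysis genes lost the call without DKO 3 (0.234). Several lists passed there only with 1 library left out. Without DKO 2 these were sarcomere genes as lower (0.000554), sex-linked genes as lower (0.0246) and, as higher, immediate early and heat shock genes and trabecular markers (each 0.0246), atrial markers (0.0311), conduction genes (0.0405) and growth factor signals (0.0419). Notch pathway genes passed as lower without DKO 3 (0.000867) or Irx4KO 3 (0.0309), erythroid markers as lower without Irx4KO 2 (0.00815), atrial markers as higher without Irx4KO 3 (0.0296), and immediate early and heat shock genes as higher without Irx4KO 4 (0.00138).

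DKO was compared with the double heterozygotes, the other genotype mutant for both genes. Within sets Pcdhac2 rose by 1.89 ± 0.24 (1.4 ± 0.132 to 5.19 ± 1.5 CPM, SD, n = 3 and 3, adjusted p = 0.0039), Tbx2 rose by 1.05 ± 0.14 (16.7 ± 2.12 to 34.5 ± 6.25 CPM, adjusted p = 0.006) and Kcnh7 rose by 1.01 ± 0.14 (adjusted p = 0.0067). Gja1 fell by 0.61 ± 0.086 (496 ± 17.5 to 325 ± 19.4 CPM, adjusted p = 0.0067), Pln fell by 0.42 ± 0.07 (adjusted p = 0.022) and Irx3 fell by 1.84 ± 0.13 (adjusted p = 1.0e-06), while Irx4 was at 0.31 (adjusted p = 0.46). Sfrp1, a secreted Wnt antagonist, rose by 0.36 (adjusted p = 0.033) and the pseudokinase gene Trib2 fell by 0.57 (adjusted p = 0.012). A total of 317 genes passed in the planned fit, 184 higher and 133 lower, and the fit within sets called 15 of them, 6 higher and 9 lower. A fit of the set 2 libraries alone, which takes the spread from those libraries only, called 173. Named in the planned fit were also Tnni2 at 1.84, Mab21l2 at 1.65, Car3 at 1.64, Mybphl at 1.52, Wif1 at -1.54, Asb11 at -1.43 and Gpr149 at -1.27, none past the threshold within sets (adjusted p from 0.11 to 0.19), and Wscd2 at -1.21, which passed there (adjusted p = 0.049). Gja1, Irx3 and Pcdhac2 passed within sets without each library. Without double heterozygote 3 the adjusted p was 0.061 for Tbx2 and Trib2, 0.064 for Kcnh7, 0.11 for Pln, 0.13 for Sfrp1 and 0.12 for Wscd2. Without DKO 4 it was 0.053 for Kcnh7, 0.11 for Trib2, 0.18 for Pln, 0.2 for Sfrp1 and 0.22 for Wscd2, and without DKO 3 0.069 for Trib2, 0.087 for Pln and Sfrp1 and 0.14 for Wscd2. Pln also lost the call without double heterozygote 2 (0.057), Sfrp1 without double heterozygote 4 (0.12) or DKO 2 (0.05), and Wscd2 without double heterozygote 2 (0.1) or 4 (0.099), DKO 2 (0.059) or DKO 10 (0.06). Atrial markers were higher as a group within sets (camera adjusted p = 1.33e-04, adjusted p = 0.0865 with an estimated correlation), as were cushion and fibroblast markers, immediate early and heat shock genes, and neural crest and neuron markers. Calcium handling genes and ventricular markers were lower. These 5 lists did not pass with an estimated correlation (adjusted p from 0.308 to 0.341). Without double heterozygote 3 the call was lost by cushion and fibroblast markers (0.374), immediate early and heat shock genes (0.195) and ventricular markers (0.18), the last also without DKO 3 (0.0797). Neural crest and neuron markers lost it without double heterozygote 4 (0.22), DKO 3 (0.0797) or DKO 5 (0.102). Passing only with 1 library left out were, as higher, cell cycle genes without DKO 3 (0.000864), DKO 7 (0.0119) or double heterozygote 3 (0.0102), glycolysis genes without DKO 4 (0.0041) or double heterozygote 2 (0.044), growth factor signals without DKO 2 (0.0214) or double heterozygote 2 (0.0133), conduction genes without DKO 2 (0.025) and smooth muscle markers without DKO 4 (0.0154). As lower these were endothelial markers without DKO 3 (0.0497) or double heterozygote 3 (0.0155), Notch pathway genes without DKO 3 (0.036) and the Irx family without DKO 4 (0.0119). The planned count was 10 without double heterozygote 3, 29 without double heterozygote 2, 98 without double heterozygote 4, 125 without DKO 10, 136 without DKO 7, 477 without DKO 4, 750 without DKO 2 and 1912 without DKO 3. The count of 15 was 4 without double heterozygote 3, 5 without DKO 4, 7 without DKO 3 and 110 without DKO 5.

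Irx3KO, Irx4KO and the double heterozygotes were each compared with WT to ask for effects of 1 gene or of reduced dose, and every such comparison coincided with the library set. In Irx3KO, Irx3 fell by 3.13 ± 0.13 in the planned fit (adjusted p = 1.4e-10) and by 3.09 ± 0.18 within sets (adjusted p = 7.8e-08). In the planned fit 68 genes passed, 49 higher and 19 lower. They included Irx1 at 1.29, Nav3 at 1.25, Srp54a at 1.23, the calcium release channel Ryr2 at 0.93 and Bbs2 at 0.92. Lower were Dcpp2 at -2.22, Kcne3 at -1.12, Clec2d at -0.73 and Rpl38 at -0.64, while Irx4 was at 0.60 (adjusted p = 0.057). Within sets 3 passed, Irx3, Ctse and Tex13b, of which the last 2 lie outside the naming rule. These and Gm43302 were singled out after their values were seen. Ctse turned sign between the fits in Irx3KO (0.35 planned, -5.37 within sets), Irx4KO (0.66 and -5.06) and double heterozygotes (0.01 and -5.71). It was at 1.93 to 2.77 CPM in WT and 0 to 0.109 CPM in DKO of set 1, so its calls within sets rest on the latter. In Irx4KO, Lyz1 was at -2.10 ± 0.26 (adjusted p = 0.0019; within sets -2.38 ± 0.37, adjusted p = 0.016) and Irx4 at 1.23 ± 0.14 (adjusted p = 0.0011; within sets 1.37 ± 0.19, adjusted p = 0.014), while Irx3 was at 0.00 ± 0.12 (adjusted p = 0.99). There 346 genes passed in the planned fit, 219 higher and 127 lower, with Abca6 at 2.14, Zim1 at 1.62, the skeletal actin Acta1 at 1.44, Elovl7 at 1.37, Ppp1r17 at -2.36, Lyz2 at -1.93 and Gtsf1 at -1.81, and 7 passed within sets. Ccl21a is given without a fold. In the double heterozygotes Irx3 was at -0.92 ± 0.12 (adjusted p = 0.005) and Irx4 at 0.95 ± 0.14 (adjusted p = 0.008), and within sets at -0.88 (adjusted p = 0.24) and 1.10 (adjusted p = 0.1). Of 570 genes that passed in the planned fit there, 370 were higher and 200 lower, with Farp2 at 1.74, Sorbs2os at 1.68, Tmc5 at 1.33, Hmcn2 at 1.30, Crh at 1.30, Hbb-bh1 at -2.13, Ppp1r17 at -1.96, Lyz2 at -1.36 and C1qa at -1.19, and 2 passed within sets, Ctse and Gm43302. The planned count for Irx3KO was 1 without any of its libraries or without WT 1, and 4 without WT 2 or WT 3. For Irx4KO it was 10 without Irx4KO 2 or Irx4KO 3, 27 without Irx4KO 4, 8 without WT 1, 21 without WT 2 and 39 without WT 3. For the double heterozygotes it was 10 without library 2, 9 without library 3, 69 without library 4, 4 without WT 1, 6 without WT 2 and 13 without WT 3. Past the threshold without each library were Irx3 in Irx3KO (planned fit), Irx4 and Lyz1 in Irx4KO (at most 0.016 and 0.021) and Irx3 in the double heterozygotes (at most 0.028). Irx4 in the double heterozygotes lost the call without WT 1 (0.057) or WT 2 (0.052). All other genes named here lost it without at least 1 library (largest adjusted p from 0.081 to 0.19). Within sets the counts of 3, 7 and 2 were 19, 97 and 36 by DESeq2 and 1, 18 and 0 by limma-voom (1318 at an unadjusted p under 0.05 for the last). They rose to 11, 67 and 16 without DKO 5. The 3 genes of Irx3KO became 5 without DKO 3 or WT 2, 6 without WT 3, and 2 without DKO 4 or DKO 10. For Irx4KO the 7 genes became 3 without DKO 4, 4 without Irx4KO 2 or 3, 11 without WT 2 or WT 3, 14 without DKO 7 and 15 without DKO 10. For the double heterozygotes the 2 genes became 1 without library 3 or WT 1, 4 without DKO 7, and 5 without library 4 or WT 3.

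The interaction asks whether the DKO differs from the sum of both single knockouts on the log scale. In the planned fit 2460 genes passed, 1163 higher and 1297 lower than the sum. This contrast is confounded with the library sets, and with the set difference simulated it called 2084 of 16191 unchanged genes. Genotype differences between the sets may be part of that simulated difference. It was led by Mcm3ap at 4.05, Grid1 at 3.42, Slc25a31 at 3.39, Ppp1r17 at 3.09 and Ranbp9 at 2.45, and by Hist1h2ad at -7.01, Mlph at -4.62, Farp2 at -2.70 and Tenm3 at -2.48, with Ccl21a given without a fold. Irx3 was at 0.39 (adjusted p = 0.11) and Irx4 at -0.49 (adjusted p = 0.07). Within sets edgeR called 0 genes, with 563 at an unadjusted p under 0.05, and DESeq2 called 12. The planned count was 696, 1261 and 1437 without WT 2, WT 3 and WT 1, 883, 972 and 1235 without Irx4KO 2, 3 and 4, 990, 1074 and 1098 without Irx3KO 2, 1 and 4, and 3763 without DKO 3. Within sets 3 genes passed without DKO 5 and 1 without Irx3KO 2.

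The effect of the mutant Irx4 allele was compared with and without Irx3 across genes, which are not independent replicates, between differences that share no library. Pearson's r between Irx4KO minus WT and DKO minus Irx3KO was -0.197 (-0.126 without WT 2), and r between Irx3KO minus WT and DKO minus Irx4KO was -0.336. The library sets enter both differences of a pair with opposite sign. Over 16191 unchanged genes with the set difference simulated r was -0.34 and -0.39, and neither real r lay below these. The simulated difference also holds genotype differences between the sets, so these are no exact values for no change. Within sets they were -0.191 and -0.295, where both differences hold the DKO libraries of set 2 with opposite sign, and -0.345 and -0.395 in the simulation.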

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

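The tests of the library sets were chosen only after the sets had been seen. In 5 of 36 measures a library lay far from the other 5 of its group of 6, where chance gives about 1 in 20. These were rho with GC in DKO 5 (0.486, others -0.153 to 0.008), Tnni2 in DKO 5 (101 CPM, others 27.8 to 53.1), Lyz2 in DKO 5 (19.7 CPM, others 7 to 11.7), Ddc in DKO 5 (77.3 CPM, others 35.5 to 50.1) and Lyz1 in DKO 4 (1.6 CPM, others 0.899 to 1.1). In the interaction term of the planned fit, which is confounded with the library sets, 2460 genes passed, where 2084 unchanged genes passed with the set difference simulated, and 0 passed within sets (edgeR, 563 at an unadjusted p under 0.05, DESeq2 12). Among 5044 transcripts not matched to a gene, 9 were higher and 8 lower in DKO than in WT within set 1.

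The libraries fell into 2 sets that follow no label. A genotype difference is excluded as the cause, since 3119 genes differed between the sets within DKO. Removing trends on transcript length and GC left 1371 of these genes past the threshold. The trends were fitted on the longest transcript and the mean GC of each gene. A removal that misses part of a trend would also leave genes, so length and GC are not excluded as the whole cause. Pseudogenes, ribosomal and histone genes were 6.69 times as frequent among the 48 genes differing at least 4-fold as among other genes (29.17% against 4.36%, Fisher's exact p = 1.18e-08). A different division of reads between near-identical copies may be part of the cause. The 48 genes were taken before the trends were removed, so their share does not tell such a division apart from the length trend. A difference in sequencing or in the authors' processing, which the labels do not give, stays open and was not tested.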

How the results depend on the processing

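The set term, the libraries of 1 set, the removed trends, the unmatched transcripts and all results within sets were chosen only after the data were seen, and where a value moved the cause was not tested unless fewer samples or genes are named. No gene named by the naming rule reversed, while Ctse, singled out later, turned sign with the set term. Of 407 named-gene results, 307 kept their side of the threshold with the set term, 83 lost it and 17 gained it; 321 kept it with only the compared groups in the fit and 84 lost it; 326 kept it with DESeq2 and 76 gained it; and 406 kept it with RLE size factors. Depth was at least 26721576 counts per library, and of 28563 genes 16607 had enough counts for the filter.

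Counts of genes past the threshold moved by over 1.5 times as follows. DESeq2 gave 315 in DKO against WT (105 in the planned fit), 1228 in Irx3KO (68), 1662 in Irx4KO (346) and 1814 in double heterozygotes (570) against WT, and 947 in DKO against Irx3KO (284), 505 against Irx4KO (12) and 1306 against double heterozygotes (317). In the same order limma-voom gave 919, 4473, 5063 and 3634, then 985 and 323, and 4764 in the interaction (2460). With only the compared groups there were 6, 3576, 4226 and 2968, then 40, 4 and 2. Counts rebuilt from TPM gave 1 in Irx3KO, 183 in Irx4KO and 144 in double heterozygotes against WT, and 182 and 138 in DKO against Irx3KO and double heterozygotes. The sex covariate gave 281 in Irx3KO and 773 in Irx4KO against WT and 181 in DKO against double heterozygotes, and no filter gave 362 in double heterozygotes against WT. The median over choices of 3 DKO libraries, with fewer samples, was 180.5 against WT, 453 against Irx3KO, 33.5 against Irx4KO and 747.5 against double heterozygotes. In the same order the choices ran from 26 to 2720, 74 to 4659, 1 to 4723 and 7 to 4981. The highest count came with DKO libraries of set 2 only against WT, and of set 1 only against the others.

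The set term gave 239 in DKO, 3 in Irx3KO, 7 in Irx4KO and 2 in double heterozygotes against WT, 63, 4 and 15 in DKO against Irx3KO, Irx4KO and double heterozygotes, and 0 in the interaction (edgeR; 563 at an unadjusted p under 0.05, DESeq2 12). Libraries of 1 set only gave 16, 179, 4 and 173 in DKO against WT, Irx3KO, Irx4KO and double heterozygotes. In these fits DKO against WT had fewer calls than DKO against Irx3KO or double heterozygotes, where the fit within sets had more. The counts of 239, 63 and 15 are therefore no ranking of effect size. With the trends removed there were 171, 5, 186 and 86 against WT, 179 in DKO against double heterozygotes and 684 in the interaction, and with the set term as well 446, 3, 10 and 3 against WT, 81, 3 and 20 in the other DKO comparisons and 0 in the interaction (edgeR; 651 at an unadjusted p under 0.05). Unmatched transcripts kept as features gave 2, 126 and 140 in Irx3KO, Irx4KO and double heterozygotes against WT and 7 and 180 in DKO against Irx4KO and double heterozygotes. Within sets, DESeq2 gave 608, 201, 26 and 178 in DKO against WT, Irx3KO, Irx4KO and double heterozygotes, removed trends gave 446 against WT, the sex covariate 38 against Irx3KO, counts rebuilt from TPM 1 against Irx4KO and limma-voom 6 against double heterozygotes.

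The replicate number as a block gave 1864 in DKO, 2906 in Irx3KO, 3103 in Irx4KO and 3279 in double heterozygotes against WT, and 41, 3 and 51 in DKO against Irx3KO, Irx4KO and double heterozygotes. The numbers do not pair the libraries: the median r of 23 same-number pairs was -0.021 (-0.308 to 0.212), 5 pairs were over 0.1, and 2 of 15 libraries correlated best with their own number.

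Lists past the threshold in DKO against WT went from 10 to 2 with an estimated correlation, 2 with fry, which tests a list against no change rather than against other genes, 6 with the set term and 0 with the set term and an estimated correlation (camera). Pearson's r of -0.197 became -0.376 by Spearman's rho and -0.327 over genes of at least 1 CPM, and r of -0.336 became -0.482 and -0.455.

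With 1 library left out, counts ran from 26 to 607 in DKO, 1 to 4 in Irx3KO, 8 to 39 in Irx4KO and 4 to 69 in double heterozygotes against WT, from 52 to 1413, 1 to 1040 and 10 to 1912 in DKO against Irx3KO, Irx4KO and double heterozygotes, and from 696 to 3763 in the interaction. Within sets they ran from 67 to 586, 15 to 142, 1 to 4 and 4 to 110 in the DKO comparisons. Lists ran from 7 to 14, and the correlations from -0.272 to -0.126 and from -0.395 to -0.246.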

Other observations

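All comparisons between Irx3KO, Irx4KO and double heterozygotes, and all tests below except the counts of other splits, were chosen only after the results were seen. Of 48 genes that differed within sets between Irx3KO and Irx4KO libraries, all of set 2, 27 were also called in DKO against WT of set 1, which share no library with them. Of these, 13 were higher in Irx3KO and lower in DKO and 9 the other way round, where independent lists would share 0.19 and 0.15, and 2 were higher and 3 lower in both. Both tests use each gene's spread over all libraries, so 0.19 and 0.15 are no exact values for unrelated lists. The genes below were singled out after their values were seen, and 21 of the 48 were not called in DKO against WT, among them Pla2g5 (-1.21), Scn10a and Cyp26a1 (-1.69). Gja1, which encodes connexin 43, was higher in Irx3KO than in libraries labelled Irx4KO by 0.73 ± 0.086 (log2 fold change ± SE, 536 ± 41.5 against 322 ± 9.04 CPM, SD, n = 3 each, adjusted p = 0.00082), and so were Ddc by 1.64 ± 0.258 (adjusted p = 0.015), the potassium channel gene Kcnk3 by 0.97 (adjusted p = 0.0012), Gpr37 by 1.51, Lyz1 by 1.65 (both adjusted p = 0.0066), Trib2 by 0.56 (adjusted p = 0.0075), Bbs2 by 0.90 (adjusted p = 0.0066) and Mt3 by 1.90 (adjusted p = 0.038). The sodium channel gene Scn10a was lower in Irx3KO (-1.14, adjusted p = 0.011), as was Irx3 (-3.14, adjusted p = 3.0e-10). Without Irx4KO 2 or Irx4KO 3 Bbs2 lost the call (0.055 and 0.059), as did Gpr37 without Irx4KO 2 (0.056), Lyz1 without Irx4KO 3 (0.059) and Trib2 without Irx4KO 2 or 4 (0.055 and 0.054). Ddc lost it without Irx3KO 4 or any Irx4KO library (0.058 to 0.12), Scn10a and Cyp26a1 without Irx3KO 2, Irx3KO 4, Irx4KO 2 or Irx4KO 3 (0.053 to 0.11) and Mt3 without any library but Irx4KO 4 (0.12 to 0.19). Of the 48 genes 24 were higher and 24 lower in Irx3KO, and 23 passed in the planned fit, 13 higher and 10 lower, where Mt3 did not pass (adjusted p = 0.051). Between libraries labelled Irx4KO and double heterozygotes 2 genes passed, Gja1 lower in Irx4KO (-0.62, adjusted p = 0.011) and Irx3 higher (0.93, adjusted p = 0.0098), of which Gja1 did not pass in the planned fit (adjusted p = 0.055), and between Irx3KO and double heterozygotes Irx3 passed (-2.21; 1 gene by edgeR, 2 without double heterozygote 2 or 4, 11 by DESeq2). The count of 48 was 12 without Irx4KO 3, 15 without Irx4KO 2, 24 without Irx4KO 4, 23 without Irx3KO 1, 21 without Irx3KO 2 and 22 without Irx3KO 4, and it was 217 by DESeq2 and 86 with the length and GC trends removed. In fits of the set 2 libraries alone the counts of 48, 2 and 1 were 145, 12 and 2. The count of 2 was 0 without Irx4KO 3 or Irx4KO 4 (edgeR, 696 and 821 at an unadjusted p under 0.05; DESeq2 with all libraries 22, limma-voom with all libraries 0, 845 at an unadjusted p under 0.05), 1 without Irx4KO 2 or double heterozygote 3, 3 without double heterozygote 4 and 6 without double heterozygote 2.

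Irx4 counts were higher in libraries labelled with mutant Irx4. In DKO the library set does not account for this, since the rise within set 1 was 1.4 on the log2 scale. Nor do length and GC trends as fitted, after whose removal it was 1.38. Within set 2 Irx4 also passed between DKO and Irx3KO, though not without each library. It was not among the 48 genes called between Irx3KO and Irx4KO, where its mean was higher in Irx4KO. Its rise in Irx4KO against WT within sets rests on the DKO libraries of both sets. All 9 libraries labelled with a homozygous mutation lay above every WT library, which had been set as excluding a swap of labels, but an exchange of whole groups would give the same. Irx3 excludes an exchange of WT with DKO, with a log2 fold change of -2.72 in DKO within set 1 and 6 of 6 DKO libraries below every WT library, so that only an exchange that keeps Irx3, such as WT with Irx4KO and Irx3KO with DKO, stays open. A counted part of Irx4 left by the deletion may account for the rise and stays open too: the share of counts on the main transcript was 10.3 points higher in DKO of set 1 than in WT with no overlap, but within set 2 it overlapped between Irx3KO (83.97% to 89.83%), not labelled mutant for Irx4, and Irx4KO (88.35% to 91.77%), a condition added after these shares were seen.

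Several changed genes lie on the chromosomes of the targeted genes, and the library set does not account for Bbs2 and Mt3 on chromosome 8, as both passed within set 2 (adjusted p = 0.037). For chromosome 13, home of Irx4, 9 of 62 genes called in DKO against Irx3KO lie there (odds ratio 4.59, 95% CI 1.98 to 9.45, Fisher's exact p = 0.000358, 0.00716 over 20 chromosomes) and 6 of 48 between Irx3KO and Irx4KO (odds ratio 3.85, 95% CI 1.33 to 9.14, exact p = 0.00728, 0.146 over 20 chromosomes). Both comparisons hold the same Irx3KO libraries and share Adgrv1, Cap2 and Elovl7, so they are not separate evidence. A stretch that came with the mutant Irx4 allele may contribute, but in DKO against WT 10 of 238 lie there (odds ratio 1.17, exact p = 0.597). The list of neighbours of Irx4, planned as a check for linked strain differences, passed camera as higher in DKO against WT within sets, at the preset correlation only. It lost the call without DKO 5 (camera adjusted p = 0.104) or DKO 7 (0.0746). In DKO against Irx3KO it pointed lower and did not pass (0.171). For chromosome 8, home of Irx3, all 3 genes called beside Irx3 in DKO against Irx4KO lie there (Adgre5, Bbs2 and Mt3, exact p = 0.000147), but the pattern was noticed in these genes, so they do not test it. A stretch that came with the Irx3 allele stays open, since 5 of 47 genes between Irx3KO and Irx4KO lie on chromosome 8, the same 3 among them (exact p = 0.101, odds ratio 2.14, 95% CI 0.659 to 5.42), 19 of 238 in DKO against WT (odds ratio 1.57, exact p = 0.0774), and 3 of 63 in DKO against Irx3KO, which are both labelled mutant for Irx3 (odds ratio 0.895, exact p = 1). The first bound set for the test between Irx3KO and Irx4KO, a p of 0.05 or more, would have excluded the stretch. It was replaced after p was seen by an upper bound on the odds ratio, because a p that misses the threshold excludes nothing. Besides 7 chosen chromosome tests, each of 20 chromosomes was tested in DKO against Irx3KO, Irx3KO against Irx4KO and DKO against WT.

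Other splits of the same libraries were counted for each comparison, and the counts of splits include the real one. Among 84 splits, 5 gave at least 105 genes in DKO against WT (highest other 2453) and 5 at least 12 in DKO against Irx4KO (highest other 5137), so chance is not excluded there. Shares under 0.05, the bound set for excluding a random division, were found for DKO against Irx3KO (284 genes, 3 of 84 splits, highest other 5003), against double heterozygotes (317 genes, 3 of 84, highest other 5148) and for the interaction (2460 genes, 2 of 100 splits, highest other 2591). Most of these splits place the library sets in the groups otherwise than the real one, so they are not like it. The shares are also not adjusted for the number of comparisons, so a random division is not excluded there. The library sets are not excluded either, since these splits mix libraries of both sets. The simulated set difference, which may hold genotype differences too, gave 2084 calls in the interaction. The splits with 2453, 5003, 5137 and 5148 genes follow the library sets, and counts several times the real one point to that structure of the samples. Chance is not excluded for the 10 lists in DKO against WT, which 7 of 84 splits matched (highest other 11). For 3 against 3 libraries, 10 splits are too few for a share under 0.05: 68, 346 and 570 genes in Irx3KO, Irx4KO and double heterozygotes against WT (1 split each, highest other 0, 0 and 1), where the real split is also that of the sets, and within sets 239, 63, 4 and 15 genes in DKO against WT, Irx3KO, Irx4KO and double heterozygotes (1, 1, 2 and 1 splits, highest other 1, 1, 11 and 0).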
